A study of Oryza sativa with 8 samples.

How the data were processed

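Transcripts were measured on 8 rice Affymetrix arrays, with 2 arrays for each combination of genotype (Hejiang19 wild type or Ghd7 overexpressor) and tissue (young leaves or panicles of 0.1 cm). Groups and replicate numbers were taken from the sample titles. The labels call the replicates biological. The values are log2 expression values deposited by the authors, made with RMA per the submitters' processing notes, and its version is not given in the sources used here. RMA corrects the background, quantile normalizes arrays and summarises the probes of each probe set. Array medians were 4.49 to 4.53 in leaves and 6.13 to 6.15 in panicles, and arrays of different tissues correlated with r of 0.644 to 0.659. A single quantile normalization would have given all arrays the same distribution, so levels were not compared across tissues without that limit, and genotype effects were taken within a tissue.

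The table held 57381 probe sets. Control probe sets, 123 of the AFFX kind and 64 reporter probe sets, were left out of the tests, which left 57194. The platform annotation paired 22436 of these with 1 gene, 95 with several and 34663 with none. Names were updated through a RefSeq gene table. The paired probe sets covered 17905 genes, of which 2453 had a name other than a locus number or clone. Coordinates are not printed. Probe sets with several genes named none.

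One mean per group was fitted to the log2 values of all 8 arrays with limma 3.58.1 in R 4.3.3, which left 4 residual degrees of freedom, and moderated with eBayes. The fit takes 1 spread per probe set for all 4 groups. The contrasts were overexpressor minus wild type in leaves, the same in panicles, the difference of those effects, and panicle minus leaf in wild type. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested probe sets within each contrast, and a probe set passed at an adjusted p under 0.05. "Rose", "fell" and "changed" refer to that test. A change is called a lower bound where the lower group mean was below the median of its arrays, since such a value may be background. Gene lists were tested with camera at its preset correlation of 0.01, on 1 probe set per gene (the highest mean over 8 arrays), for lists with at least 5 measured genes, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

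10 gene lists with 145 entries, the tests, the rule for named genes and most alternatives were fixed before the data were examined, and 94 entries were matched to a measured gene. The list of leaf senescence and chlorophyll breakdown had 3 measured genes and was not tested. A further 20 lists meant to match gene descriptions could not be run, because the tables hold symbols and no descriptions. They were replaced by 33 family lists built from symbols, which were written after the annotation and the largest single changes had been seen, before any list was tested. The flowering, clock, meristem, floral, gibberellin, cytokinin, abscisic acid, defence and nitrogen lists are the fixed ones that were tested. Photosynthesis, ribosomal, MADS, AP2/ERF and the others are family lists.

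The named genes were every measured flowering gene, the 10 largest rises and falls per tissue among named genes whose transgenic values both lay beyond both wild-type values, up to 4 members with the smallest p of other lists, and the 5 largest differences each way for the last pair of contrasts. List members beyond these were printed to complete the floral and meristem lists and to give every member of a short count. Of the family lists, members were named as such only where the list passed in a tissue, apart from IAA3, IAA31, OsChia2a and Os4bglu13, which are named for a probe set of the opposite sign.

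On simulated data with the means and spread of these arrays, 54 of 100 probe sets changed by a log2 value of 1 and 95 of 100 changed by 2 were recovered in the leaf contrast over 57194 probe sets, with 6 false calls. In the panicle contrast 61 and 94 were recovered, with 8 false calls. In a simulated leaf contrast over 15000 genes, a list of 15 genes moved by a log2 value of 0.5 was called, as were 0 of 39 lists that were not moved. Simulated values were drawn independently for each probe set. They therefore say nothing of false calls for lists whose genes vary together. Each probe set was also given the same spread in all groups, as the fit assumes, and few probe sets were changed. The counts of false calls therefore do not cover groups that differ in spread, as the real ones did. The alternatives were 3 normalizations, 2 filters on dim probe sets, a fit on the 4 arrays of a comparison, an intensity trend with a robust prior, array weights, replicate terms, 1 probe set per gene, a test against a 1.2-fold change and leaving out each array. Groups of 2 arrays are too small for a test of single arrays as outliers or for other splits of the samples.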

Results

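The series measured transcript levels with a rice Affymetrix array in Hejiang19, a rice cultivar, and in transgenic plants of that background that overexpress Ghd7, a regulator of flowering time, plant height and grain number. Young leaves of 35-day-old field-grown plants and developing panicles of 0.1 cm were taken from both genotypes. All samples were taken 3 hours after dawn, so genes that cycle over the day were seen at a single time. Each of the 4 groups held 2 arrays, labelled as biological replicates, so 8 arrays were compared. After removal of control probe sets, 57194 probe sets were tested. The number of arrays limits the precision: the median SD between replicates was 0.12 on the log2 scale in wild-type leaves, 0.10 in transgenic leaves, 0.07 in wild-type panicles and 0.10 in transgenic panicles. Replicates correlated with r of 0.991 to 0.998 across probe sets, which are not independent replicates. Ghd7 itself and Ehd1 are not analysed here, since no probe set was paired with either name, so the overexpressed gene gave no check of the labels.

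The first comparison asked which transcripts differ between Ghd7 overexpressors and wild type in young leaves. The florigen gene Hd3a, whose product moves from leaves to the shoot apex and triggers flowering, fell from 10.59 ± 0.02 (SD, n = 2) to 3.84 ± 0.48 on the log2 scale, at least 107-fold (limma, adjusted p = 1.14e-06). OsMADS14, an APETALA1-like gene that acts with florigen in the floral transition, fell from 11.28 ± 0.34 to 4.03 ± 0.12, at least 152-fold (adjusted p = 1.26e-07). The related OsMADS18 changed by -2.02 ± 0.14 (log2 ± SE) and OsMADS34 by -1.25 ± 0.21. OsMADS1, a SEPALLATA-like floral gene, changed by -6.26 ± 0.28. In transgenic leaves Hd3a, OsMADS14 and OsMADS1 lay at percentiles 36.9, 40.9 and 35.8 of the array, where a value may be background, so these falls are lower bounds. Both values of OsMADS34 (32.8 and 6.99) were below the array median (percentiles in brackets), so the size of the change is uncertain. OsMADS50, an activator of flowering, rose by 0.50 ± 0.12 with adjusted p = 0.0480. After quantile normalization of all arrays again, array medians set equal, array weights or a test against a 1.2-fold change, OsMADS50 did not pass. OsMADS50 (adjusted p = 0.0544 to 0.182) did not pass without any of the 8 arrays. OsMADS34 (adjusted p = 0.0522 to 0.102) did not pass without transgenic leaf replicate 1 or 2.

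Of 18 measured flowering time genes, 4 fell, 1 rose and 13 did not pass the test over all probe sets. Adjusted over the list alone, 5 fell and 1 rose. The list as a whole did not pass (adjusted p = 0.0828 by camera and adjusted p = 0.732 with an estimated correlation). Upstream photoperiod genes were among those that did not pass: the change was -0.14 ± 0.14 for Hd1, a CONSTANS-like gene, -0.01 ± 0.15 for DTH8, -0.27 ± 0.21 for OsPRR37, 0.06 ± 0.18 for OsGI and 0.36 ± 0.13 for OsMADS56. Hd1 had a wild-type leaf value of 2.59 ± 0.10 and DTH8 of 3.72 ± 0.12, at percentiles 12.4 and 35.7, so a fall could have gone unseen. Values were -0.30 for OsMADS15, -0.35 for Ehd3, 0.02 for Ehd4, -0.03 for Hd16 and 0.03 for SE5, and 0.03 for OsPHYA, -0.52 for OsPHYB and -0.21 for OsPHYC. OsMADS15 lay at percentile 49.1 in wild-type leaves and 43.0 in transgenic leaves, so a fall of it could also have gone unseen.

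**Figure D1:**
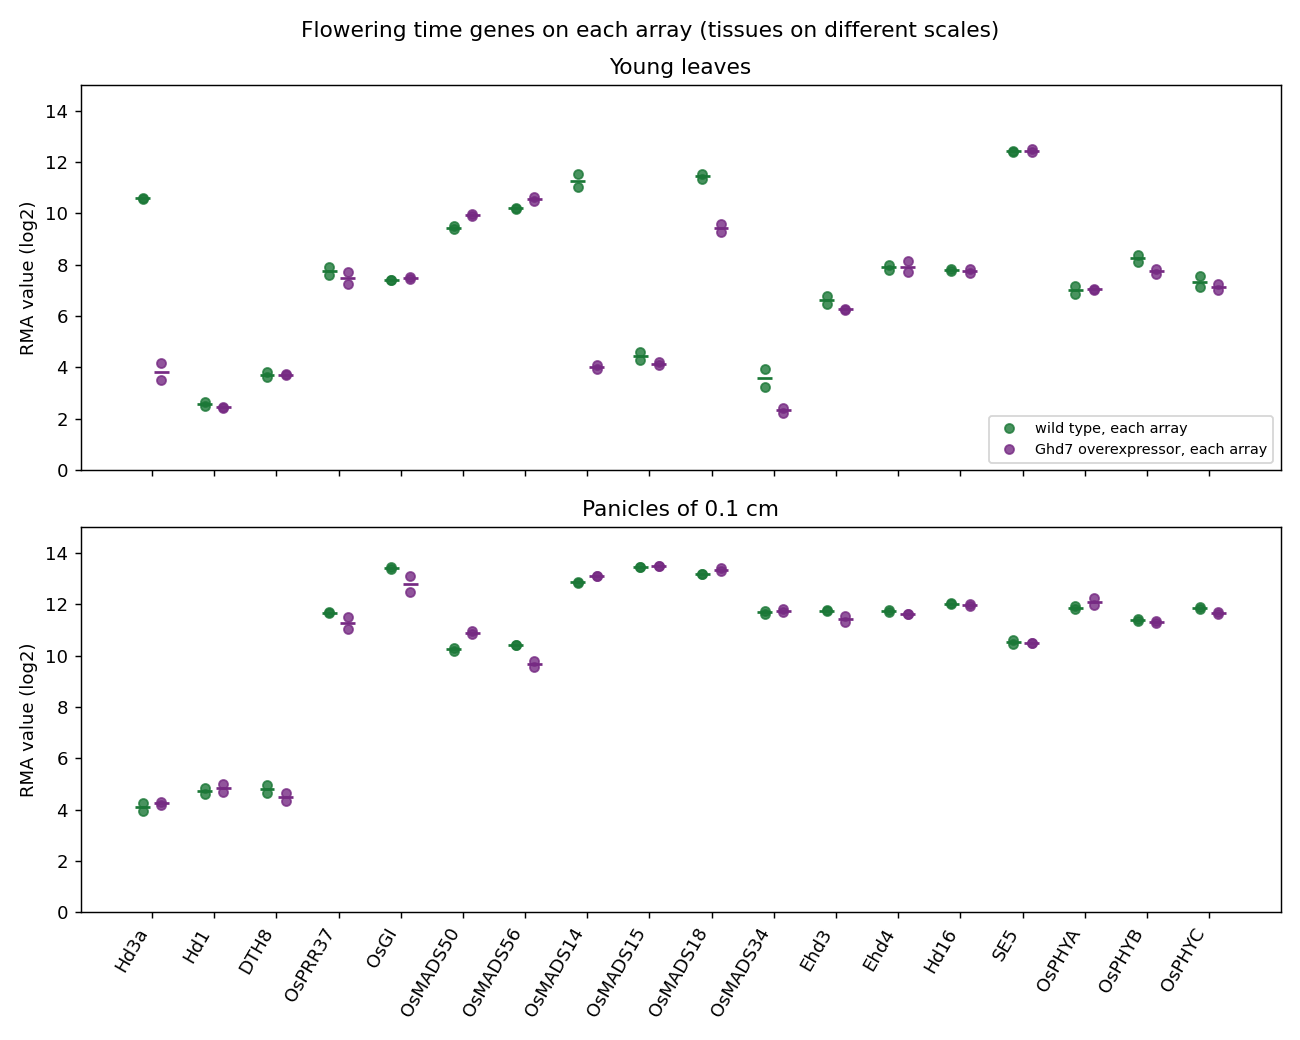
RMA values (log2, vertical axis) of the 18 measured flowering time genes on each array, with young leaves above and panicles below. Points are arrays and short lines are means of 2 arrays. Hd3a lies at 10.59 in wild-type leaves and 3.84 in transgenic leaves, against 4.10 and 4.24 in panicles.

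DREB1G, a member of the DREB1 family of cold-responsive transcription factors, rose by 4.34 ± 0.33 (at least 20.3-fold, from percentile 22.7 in wild type, adjusted p = 2.07e-04), OsDREB1B by 2.91 ± 0.17 and OsDREB1A by 2.55 ± 0.16. 4 of the 9 genes on the AP2/ERF list rose, and none of the 9 fell, with 4 up and 0 down adjusted over the list alone (adjusted p = 0.00226 by camera and adjusted p = 0.624 with an estimated correlation). The other member that rose was OsDREB1E at 0.61, and the list's median was 0.07. This family list holds only genes whose symbol matched the family, and it was written after the largest single changes had been seen. Most measured genes have no name, so other AP2/ERF genes may be missing from it, and its result does not describe the whole family. DREB1G, OsDREB1B and OsDREB1A are among the largest rises, so the list's p-value may partly restate them. OsABA8ox1, an enzyme of abscisic acid breakdown, rose by 3.39 ± 0.17. The lower value of OsABA8ox1 (36.9) was below the array median (percentile in brackets), so this change is a lower bound. Among 14 abscisic acid and drought genes, 3 rose and 2 fell over all probe sets, and 3 and 3 adjusted over the list alone (adjusted p = 0.367 by camera and adjusted p = 0.732 with an estimated correlation). Those that passed were OsABA8ox1, OsDREB1A and OsDREB1B upwards, and RAB16C at -0.77 and DIP1 at -0.82. Other probe sets of DIP1 read -0.11 and -0.087 and did not pass. OsDREB1E (adjusted p = 0.0654 to 0.143) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 1 or 2 or wild-type panicle replicate 1 or 2. RAB16C (adjusted p = 0.0595 to 0.168) did not pass without wild-type leaf replicate 1 or 2, transgenic leaf replicate 2 or wild-type panicle replicate 1 or 2. DIP1 (adjusted p = 0.0580 to 0.136) did not pass without wild-type leaf replicate 1 or 2, transgenic leaf replicate 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. The AP2/ERF factors list (adjusted p = 0.0530) did not pass without wild-type leaf replicate 2.

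Ribosomal protein transcripts were lower in transgenic leaves. 14 of 26 measured members fell and none rose, or 17 adjusted over the list alone, with a median of -0.60 (adjusted p = 3.64e-09 by camera and adjusted p = 0.624 with an estimated correlation). The change was -1.08 for RPL11, -1.03 for RPL7A-2, -1.01 for RPS7 and -0.85 for RPS4. Of 18 phosphate transporter and SPX genes, 2 rose, with 3 up and 0 down adjusted over the list alone (adjusted p = 0.0473 by camera and adjusted p = 0.653 with an estimated correlation). These were OsSPX1 at 1.16 and OsPHO1;3 at 0.97. The other 39 lists did not pass, with adjusted p from 0.0828 to 0.997 by camera. Without wild-type leaf replicate 1 the number of lists that passed was 9, and without replicate 2 it was 1. OsSPX1 (adjusted p = 0.0536 to 0.183) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsPHO1;3 (adjusted p = 0.0556 to 0.0954) did not pass without wild-type leaf replicate 2 or transgenic leaf replicate 1 or 2. The phosphate transporters and SPX list (adjusted p = 0.103 to 0.177) did not pass without wild-type leaf replicate 2 or transgenic leaf replicate 2. With quantile normalization of all arrays again that list had adjusted p = 0.0638.

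Of the lists fixed beforehand, the remaining ones held few called genes in leaves. Among 7 gibberellin genes 1 rose and 0 fell over all probe sets, and 1 and 0 adjusted over the list alone (adjusted p = 0.951 by camera and adjusted p = 0.998 with an estimated correlation), with OsKO2 at 0.54. Among 7 cytokinin genes 0 rose and 2 fell over all probe sets, and 1 and 2 adjusted over the list alone (adjusted p = 0.955 by camera and adjusted p = 0.998 with an estimated correlation), with the response regulators OsRR1 at -1.08 and OsRR4 at -0.98. Among 15 defence and jasmonate genes 1 rose and 1 fell over all probe sets, and 3 and 2 adjusted over the list alone (adjusted p = 0.490 by camera and adjusted p = 0.732 with an estimated correlation), with OsAOS2, an allene oxide synthase, at 0.64 and OsWRKY76 at -0.78. Among 13 floral organ identity genes 0 rose and 1 fell over all probe sets, and 0 and 1 adjusted over the list alone (adjusted p = 0.826 by camera and adjusted p = 0.906 with an estimated correlation), with OsMADS1 as the member that passed. By limma no gene passed among 6 clock genes, of which 2 had an unadjusted p under 0.05 (adjusted p = 0.613 by camera and adjusted p = 0.906 with an estimated correlation), among 6 panicle meristem genes, of which 1 did (adjusted p = 0.658 by camera and adjusted p = 0.841 with an estimated correlation), or among 5 nitrogen genes, of which 1 did (adjusted p = 0.990 by camera and adjusted p = 0.998 with an estimated correlation). Adjusted over the list alone, 2 clock genes passed, both downwards, and 0 meristem and 0 nitrogen genes. The median and the mean differed in sign for the floral genes (0.01 and -0.50) and the cytokinin genes (0.00383 and -0.13), and the gibberellin list had a median of -0.06 where camera gave an upward direction. Another probe set of OsKO2 read 0.28 and did not pass. OsKO2 (adjusted p = 0.0523 to 0.122) did not pass without wild-type leaf replicate 1 or 2, transgenic leaf replicate 1 or 2 or wild-type panicle replicate 1 or 2. OsRR1 (adjusted p = 0.0840 to 0.223) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsRR4 (adjusted p = 0.0638) did not pass without transgenic leaf replicate 1. OsAOS2 (adjusted p = 0.0681 to 0.157) and OsWRKY76 (adjusted p = 0.0523 to 0.148) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 1 or 2 or wild-type panicle replicate 1 or 2.

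The remaining large rises among named genes in leaves were 2.79 for OsMFT1, 2.63 for OsChia4a, 2.46 for CML31, 2.35 for OsBURP02, 2.32 for OsMADS57 and 2.29 for CML15. CML15 and CML31 belong to the calmodulin-like family and OsChia4a to the chitinases. The remaining large falls were -3.50 for PRIN2, -3.12 for OsPIP2;5, -2.66 for OsCHS1, -2.44 for OsKO5, -2.40 for mfs1, -2.23 for OsZIP4 and -2.17 for OsAT4. OsPIP2;5 is an aquaporin, OsCHS1 a chalcone synthase of flavonoid synthesis and OsZIP4 a zinc transporter. The lower value of OsChia4a (42.6), OsMADS57 (37.7), PRIN2 (27.5), OsPIP2;5 (49.1), OsKO5 (14.1) and OsAT4 (39.7) was below the array median (percentile in brackets), so these changes are lower bounds and their order is uncertain. Another probe set of OsCHS1 read -1.80 and did not pass. OsAT4 (adjusted p = 0.0651) did not pass without transgenic leaf replicate 2. In all, 2529 probe sets passed in leaves, 782 higher and 1747 lower in the overexpressor, of which 268 and 674 changed at least 2-fold. They covered 477 genes with a rise and 1222 with a fall. The fit shares 1 spread over the groups, although the median SD was 0.12 in wild-type leaves and 0.07 in wild-type panicles. The number of leaf calls may therefore be too high, and array weights gave 1767. With only the 4 leaf arrays in the fit, which leaves fewer residual degrees of freedom, 325 passed, and genes given here that lost their call had an adjusted p of 0.0751 for OsBURP02, 0.0539 for CML15, 0.0844 for OsPIP2;5, 0.0573 for OsCHS1, 0.0706 for mfs1, 0.0535 for OsZIP4, 0.103 for OsAT4, 0.180 for OsMADS50, 0.133 for OsMADS34, 0.147 for OsKO2, 0.0952 for OsRR4, 0.244 for OsRR1, 0.137 for RAB16C, 0.159 for OsWRKY76, 0.154 for OsAOS2, 0.0507 for RPS7, 0.0570 for RPS4, 0.148 for OsDREB1E, 0.114 for OsPHO1;3, 0.195 for OsSPX1 and 0.190 for DIP1. Without transgenic leaf replicate 1 the count was 1422, without replicate 2 it was 1051, and without either wild-type panicle array it was 1528. Without wild-type leaf replicate 1 it was 3292, 1318 higher and 1974 lower.

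The second comparison put the same genotypes side by side in panicles of 0.1 cm. Genes that specify floral organs were lower in transgenic panicles. OsMADS58, a class C gene of stamen and carpel identity, fell from 10.11 ± 0.02 (SD, n = 2) to 6.60 ± 0.56, which is 11.3-fold (limma, adjusted p = 1.33e-04). OsMADS7, a SEPALLATA-like gene, fell from 11.73 ± 0.02 to 8.52 ± 0.07, which is 9.29-fold (adjusted p = 5.75e-05). Of 13 measured floral organ identity genes, 9 fell and none rose, or 12 adjusted over the list alone (adjusted p = 1.91e-16 by camera and adjusted p = 0.0329 with an estimated correlation). The other genes that fell over all probe sets were the SEPALLATA-like OsMADS8 at -1.98 ± 0.12, the class B genes OsMADS16 at -1.99 ± 0.20, OsMADS4 at -1.91 ± 0.20 and OsMADS2 at -0.61 ± 0.12, the class C gene OsMADS3 at -1.58 ± 0.22, OsMADS13 at -0.80 ± 0.16 and the carpel gene DL at -1.49 ± 0.14. Those that did not pass were OsMADS1 at -0.96 ± 0.28, OsMADS5 at -0.14 ± 0.13, OsMADS6 at -0.52 ± 0.15 and OsMADS17 at -0.78 ± 0.22. Both values of OsMADS13 (49.3 and 37.3) were below the array median (percentiles in brackets), so the size of the change is uncertain. OsMADS3 (adjusted p = 0.0627 to 0.0746) did not pass without wild-type panicle replicate 1 or transgenic panicle replicate 2. OsMADS2 (adjusted p = 0.0514 to 0.229) did not pass without transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsMADS13 (adjusted p = 0.0562 to 0.244) did not pass without any of the 8 arrays.

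Genes of the panicle meristem moved the other way. 3 of 6 measured genes rose over all probe sets and 5 adjusted over the list alone (adjusted p = 1.86e-06 by camera and adjusted p = 0.0780 with an estimated correlation). OsSPL14, a regulator of branching, rose by 1.09 ± 0.12, FZP, a spikelet meristem gene, by 0.99 ± 0.18, and LOG, a cytokinin-activating enzyme of the meristem, by 0.81 ± 0.12. Values were 0.50 ± 0.14 for LAX1, 0.41 ± 0.11 for RFL and 0.22 ± 0.11 for OSH1, which did not pass over all probe sets. Another probe set of LOG read 0.10 and did not pass. The LOG probe set that rose lay at percentile 98.5 in wild-type leaves and 73.1 in wild-type panicles, so its signal is not particular to the meristem. FZP (adjusted p = 0.0507 to 0.156) did not pass without transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1. LOG (adjusted p = 0.0548 to 0.0852) did not pass without wild-type panicle replicate 1 or 2 or transgenic panicle replicate 2. Photosynthesis genes, markers of green tissue, moved down with the floral genes: 4 of 10 fell, or 5 adjusted over the list alone, with a median of -0.53 (adjusted p = 2.62e-04 by camera and adjusted p = 0.178 with an estimated correlation). These were -1.79 for RCABP69, -1.34 for OsrbcS, -0.94 for LHCP and -0.73 for GOS5. The lower value of RCABP69 (28.3) was below the array median (percentile in brackets), so this change is a lower bound. Other probe sets of OsrbcS read 0.031 and 0.23 and did not pass. RCABP69 (adjusted p = 0.0932 to 0.104) did not pass without wild-type panicle replicate 1 or 2. OsrbcS (adjusted p = 0.0542) did not pass without wild-type panicle replicate 2. LHCP (adjusted p = 0.0541 to 0.202) did not pass without wild-type leaf replicate 1 or 2, transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 2. GOS5 (adjusted p = 0.0658 to 0.135) did not pass without wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1.

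**Figure D2:**
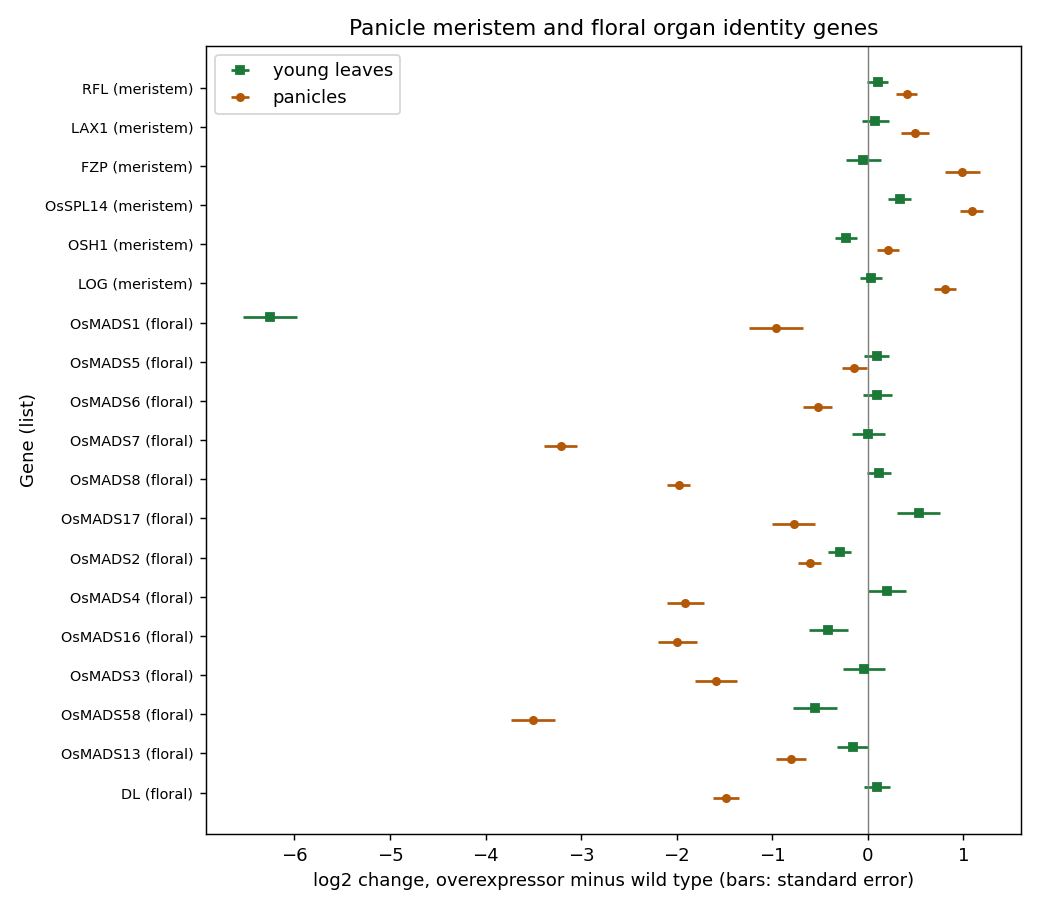
Change between overexpressor and wild type (log2, horizontal axis) for 6 panicle meristem genes and 13 floral organ identity genes, with squares for young leaves, circles for panicles and bars for the standard error. OsMADS58 lies at -3.50 and OsSPL14 at 1.09 in panicles, and OsMADS1 at -6.26 in leaves.

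Other families followed in panicles. 10 of 31 MADS box factors fell and 1 rose, or 14 and 3 adjusted over the list alone (adjusted p = 2.65e-05 by camera and adjusted p = 0.0780 with an estimated correlation), a list that shares members with the floral list. 7 of 53 homeobox and YABBY factors fell and 1 rose, with 1 up and 11 down adjusted over the list alone (adjusted p = 0.0207 by camera and adjusted p = 0.803 with an estimated correlation). Only 1 of 34 kinesins passed, KIN14F at -0.51, while the list's median was -0.27 with 2 up and 7 down adjusted over the list alone (adjusted p = 2.78e-04 by camera and adjusted p = 0.555 with an estimated correlation). By limma no single member of 49 cell cycle and replication genes passed, 7 had an unadjusted p under 0.05, and the median was -0.12 with 0 up and 0 down adjusted over the list alone (adjusted p = 0.0179 by camera and adjusted p = 0.742 with an estimated correlation). By limma none of the 6 clock genes passed, 2 had an unadjusted p under 0.05, 2 fell adjusted over the list alone, and the median was -0.32 (adjusted p = 0.0178 by camera and adjusted p = 0.652 with an estimated correlation). Of 7 dehydrin and LEA genes 1 rose, RAB16B, with 2 up and 0 down adjusted over the list alone and a median of 0.36 (adjusted p = 0.00190 by camera and adjusted p = 0.178 with an estimated correlation). The other 33 lists did not pass, with adjusted p from 0.0576 to 0.981 by camera. KIN14F (adjusted p = 0.0642 to 0.272) did not pass without transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. The circadian clock list (adjusted p = 0.0616) and the homeobox and YABBY factors list (adjusted p = 0.0616) did not pass without transgenic panicle replicate 2. The cell cycle and DNA replication list (adjusted p = 0.0620 to 0.252) did not pass without wild-type panicle replicate 1 or transgenic panicle replicate 2.

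Among 18 flowering time genes 1 rose and 1 fell over all probe sets, and 1 and 2 adjusted over the list alone (adjusted p = 0.699 by camera and adjusted p = 0.921 with an estimated correlation). OsMADS50 rose by 0.63 ± 0.12 and OsMADS56 changed by -0.75 ± 0.13. The flowering genes that fell most in leaves read 0.26 ± 0.16 for OsMADS14 and 0.14 ± 0.21 for Hd3a in panicles and did not pass. Among 14 abscisic acid and drought genes 2 rose and 0 fell over all probe sets, and 3 and 1 adjusted over the list alone (adjusted p = 0.107 by camera and adjusted p = 0.497 with an estimated correlation), with RAB16B at 2.49, a lower bound, and OsNAC6 at 0.79. Other probe sets of OsNAC6 read 0.28 and -0.058 and did not pass. Among 15 defence and jasmonate genes 1 rose and 0 fell over all probe sets, and 1 and 0 adjusted over the list alone (adjusted p = 0.885 by camera and adjusted p = 0.921 with an estimated correlation), with PBZ1 as the member that rose, and camera gave a downward direction where fry gave an upward one. Among 5 nitrogen genes 0 rose and 1 fell over all probe sets, and 1 and 2 adjusted over the list alone (adjusted p = 0.426 by camera and adjusted p = 0.921 with an estimated correlation), with OsNIA1, a nitrate reductase, at -1.48 ± 0.13. Another probe set of OsNIA1 read 0.054 and did not pass. By limma no gene passed among 7 gibberellin genes, of which 3 had an unadjusted p under 0.05 (adjusted p = 0.426 by camera and adjusted p = 0.921 with an estimated correlation), or 7 cytokinin genes, of which 3 did (adjusted p = 0.643 by camera and adjusted p = 0.921 with an estimated correlation). Adjusted over the list alone, 0 gibberellin genes passed, and among cytokinin genes 1 rose and 1 fell. OsMADS50 (adjusted p = 0.0817 to 0.237) and OsNAC6 (adjusted p = 0.0711 to 0.154) did not pass without wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsMADS56 (adjusted p = 0.108 to 0.143) did not pass without wild-type panicle replicate 1 or 2 or transgenic panicle replicate 2.

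The largest rises among named genes in panicles were 3.03 for OsHsf-05, 2.49 for RAB16B, 2.44 for PBZ1, 1.84 for HSP81-3 and 1.80 for ML6, followed by 1.70 for OsNAS3, 1.69 for OsEXPB11, 1.45 for Osem, 1.38 for OsAOX1A and 1.35 for OsHsp16.9B. OsHsf-05 is a heat shock factor, RAB16B a dehydrin, PBZ1 a pathogenesis-related protein and OsNAS3 a nicotianamine synthase. Further large falls were -1.87 for OsYAB1, -1.79 for RCABP69, -1.69 for OsMEL1 and -1.56 for PCF5. OsMEL1 is an Argonaute of germ cells. The lower value of RAB16B (29.8) and RCABP69 (28.3) was below the array median (percentile in brackets), so these changes are lower bounds and their order is uncertain. Both values of OsAOX1A (16.5 and 42.3) were below the array median (percentiles in brackets), so the size of the change is uncertain. Other probe sets of HSP81-3 read -0.065, -0.020, 0.53 and 0.11 and did not pass. HSP81-3 (adjusted p = 0.0685 to 0.122), OsHsp16.9B (adjusted p = 0.0666 to 0.0703) and RCABP69 (adjusted p = 0.0932 to 0.104) did not pass without wild-type panicle replicate 1 or 2. OsAOX1A (adjusted p = 0.0669 to 0.120) did not pass without wild-type panicle replicate 1 or 2 or transgenic panicle replicate 2. In all, 1652 probe sets passed in panicles, 600 higher and 1052 lower in the overexpressor, of which 204 and 461 changed at least 2-fold. They covered 333 genes with a rise and 404 with a fall. Without wild-type panicle replicate 1 the count was 468, without wild-type replicate 2 it was 420, and without transgenic panicle replicate 2 it was 770. Only the 4 panicle arrays in the fit gave 692, where genes that lost their call had an adjusted p of 0.0613 for RAB16B, 0.114 for HSP81-3, 0.0508 for OsAOX1A, 0.0696 for OsHsp16.9B, 0.125 for RCABP69, 0.0745 for OsMADS50, 0.0772 for OsMADS56, 0.117 for FZP, 0.0547 for OsNAC6, 0.0709 for OsrbcS, 0.0679 for GOS5, 0.147 for LHCP, 0.0741 for KIN14F, 0.0559 for OsMADS2 and 0.127 for OsMADS13, and array weights gave 2807.

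The third comparison tested whether the genotype effect differed between tissues. Among genes with a name other than a locus number, the largest differences (panicle effect minus leaf effect, log2 ± SE) were 7.51 ± 0.23 for OsMADS14, 6.89 ± 0.29 for Hd3a and 5.30 ± 0.40 for OsMADS1, which fell in leaves. Among the same genes, those in the other direction were -4.45 ± 0.46 for DREB1G, -3.22 ± 0.25 for OsMADS7 and -3.16 ± 0.24 for OsABA8ox1. Hd3a was at percentile 14.0 in wild-type panicles and OsMADS7 at 26.3 in wild-type leaves, where a fall could hardly be seen, so for these genes the difference restates the fall in the other tissue. The leaf changes behind OsMADS14, Hd3a, OsMADS1, DREB1G and OsABA8ox1 are lower bounds, so the sizes and the order are uncertain. In all 2195 probe sets differed, 1200 with a higher and 995 with a lower effect in panicles (limma interaction contrast, Benjamini-Hochberg). The effects compared were on the different scales of the tissues. After quantile normalization of all arrays again 2030 probe sets differed, and 1800 of them were among the 2195. The count was 1285 and 1116 without transgenic leaf replicates 1 and 2. Leaving out a panicle array also turned the balance: 331 higher and 339 lower without wild-type replicate 1 (total 670), 298 higher and 332 lower without wild-type replicate 2 (total 630), 693 higher and 810 lower without transgenic replicate 1 (total 1503) and 598 higher and 611 lower without transgenic replicate 2 (total 1209). Of the 2529 probe sets called in leaves, 1196 also differed between tissues, as did 873 of the 1652 called in panicles.

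Of the probe sets called in either tissue, 33 rose in both, where 8.20 would be shared by independent lists of those sizes, and 21 fell in both, where 32.1 would be. 25 rose in leaves and fell in panicles, against 14.4, and 31 fell in leaves and rose in panicles, against 18.3. The comparisons share no arrays, although they share the fitted spread. Across all probe sets, which are not independent replicates, the changes in the tissues had r = 0.063 and rho = 0.054.

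**Figure D3:**
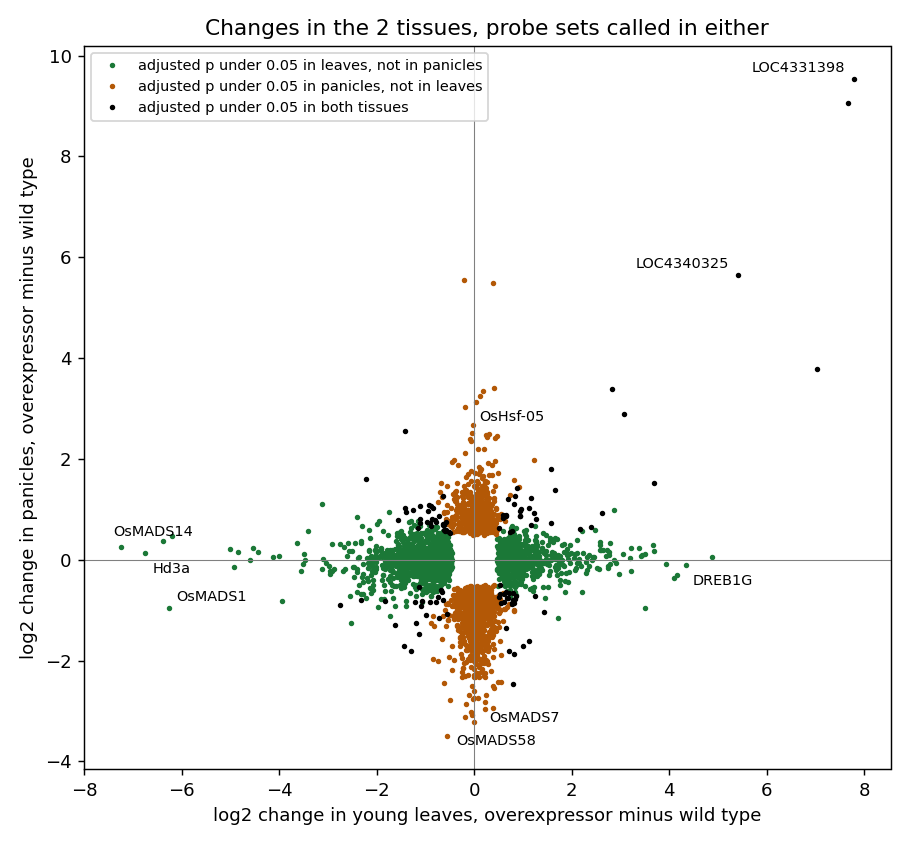
Change between overexpressor and wild type in young leaves (log2, horizontal axis) and panicles (log2, vertical axis) for probe sets that passed in leaves, panicles or both, coloured by where they passed. OsMADS14 lies at -7.25 in leaves and 0.26 in panicles, and LOC4331398 at 7.79 and 9.54.

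The last comparison described the tissues in wild type. Levels could not be set side by side directly, because the values of each tissue were on their own scale: the mean log2 value was 5.02 to 5.04 on leaf arrays and 6.94 to 6.95 on panicle arrays. As deposited, 52612 probe sets passed, 48108 higher and 4504 lower in panicles, with a median shift over all probe sets of 1.58. After quantile normalization of all arrays again, 44003 passed, 20562 higher and 23441 lower. The share higher in panicles was 91.4% as deposited and 46.7% after. Ranks within each array do not depend on the scale and were given no test. Photosynthesis genes had a median percentile of 99.8 in wild-type leaves and 60.9 in wild-type panicles. Floral organ identity genes had 28.4 and 90.8, and panicle meristem genes 28.4 and 96.4. The named genes with the largest positive differences were OsYAB3, CYCB2, OsMADS5, OSH1 and OsGLU8. OsYAB3 moved from percentile 16.6 to 99.2 and OSH1, a meristem homeobox gene, from 16.7 to 98.9. The largest negative differences were for PDX12, LTP, OsPEX11-4, OsCRSH2 and Cht11, with PDX12 at percentile 99.8 in leaves and 25.3 in panicles. The lower values may be background, so the order is uncertain.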

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

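Of the tests of explanations in this part, those on wild-type RNA, on the scale of the panicle arrays and on leaf tissue were chosen only after the results they measure had been seen, and the test on stage was set before its own result, but after single floral genes and the ranks of OSH1, a meristem gene, had been seen.

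Control probe sets of the reporter kind were outside the main measurement, and 2 of the 64 were high in transgenic leaves. RPTR-Os-K01193-1_at read 3.55 in wild-type leaves and 11.36 in transgenic leaves, a difference of 7.81 ± 0.12 (log2 ± SE, limma adjusted p = 1.04e-08), a lower bound since the wild-type value was below the array median. RPTR-Os-A00196-1_s_at differed by 8.15 ± 0.61 (adjusted p = 1.97e-04). In panicles the differences were 0.27 and 0.01, and 0 of the 64 passed by limma, with 7 at an unadjusted p under 0.05. The other 62 differed in leaves by -0.79 to 0.46. What these probe sets detect is not named in the tables used here.

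That the transgenic panicle arrays hold wild-type RNA is argued against by 5 of the 10 probe sets with the largest leaf rises also passing as rises in panicles, although 2 of them measure the same gene, LOC4331398, so they stand for at most 4 genes. That the scale of panicle arrays hides such a change is argued against by a largest measured panicle rise of 9.54, above the measured 7.81 and 8.15 of the reporter probe sets in leaves, which shows that these arrays could display a difference of that measured size. With 5 shared probe sets among those 10, the leaf and panicle samples may still come from different transgenic lines or constructs, or the reporter may be silent in panicles, and neither was tested.

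Floral organ identity genes were lower in transgenic panicles, and the median difference from the leaf effect was -1.54, which mostly restates that fall, since their median percentile was 28.4 in wild-type leaves and left little room to fall there. Leaf tissue in the transgenic panicle samples is argued against by photosynthesis genes, whose median change was -0.53 with an upper quartile of -0.16, where added leaf would raise them. A younger stage of the transgenic panicles is consistent with the rise of the panicle meristem and branching list (camera, adjusted p = 1.86e-06, median 0.65), although that list had an adjusted p = 0.0780 with an estimated correlation. LOG, a member of that list that rose, ranked higher in wild-type leaves than in wild-type panicles. Stage and an effect of the transgene at a fixed stage both remain open, since panicles were matched by length. Plant age is not given for the panicles, so whether it differed between genotypes cannot be told.

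Tests of the difference between tissues singled out 75 named or unnamed probe sets among those the text may name, with interaction adjusted p from 6.08e-06 to 0.0488 (limma). Values below are the panicle effect minus the leaf effect on the log2 scale. For a gene low in 1 tissue, such as Hd3a in panicles (percentile 14.0) or OsMADS58 in leaves (percentile 12.2), a fall could hardly be seen there, so the difference restates the fall in the other tissue. At least 1 group mean was below the array median for 46 of the 75, and the size of those differences is uncertain. Flowering genes gave 7.51 for OsMADS14, 6.89 for Hd3a, 2.17 for OsMADS18, 1.31 for OsMADS34 and -1.11 for OsMADS56. Among floral genes the difference was 5.30 for OsMADS1, -3.22 for OsMADS7, -2.95 for OsMADS58, -2.11 for OsMADS4 and -2.10 for OsMADS8. It was also -1.58 for DL, -1.58 for OsMADS16 and -1.54 for OsMADS3, and -2.27 for OsMADS57, another MADS box factor. Meristem genes had 0.76 for OsSPL14 and 0.77 for LOG. YABBY and homeobox genes had -1.80 for OsYAB2, -1.59 for OsYAB1, -1.49 for OsYAB7, -1.71 for OsHox8, -1.52 for OsHox1 and -1.02 for OsHox2. Leaving out 1 array in turn, 38 of the 75 kept the call in every fit and 37 lost it in at least 1. OsYAB2 (adjusted p = 0.0515) did not pass without wild-type panicle replicate 1. OsYAB1 (adjusted p = 0.0523 to 0.0895) did not pass without wild-type leaf replicate 1, transgenic leaf replicate 1, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1. OsMADS16 (adjusted p = 0.0543 to 0.0960) did not pass without wild-type leaf replicate 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsMADS3 (adjusted p = 0.0760 to 0.130) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsYAB7 (adjusted p = 0.0515 to 0.0556) did not pass without wild-type panicle replicate 1 or 2. OsMADS56 (adjusted p = 0.0556 to 0.0700) did not pass without transgenic leaf replicate 2 or wild-type panicle replicate 1 or 2. OsHox2 (adjusted p = 0.0561 to 0.121) and OsMADS34 (adjusted p = 0.0984 to 0.175) did not pass without transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsSPL14 (adjusted p = 0.0762 to 0.204) and LOG (adjusted p = 0.0595 to 0.157) did not pass without wild-type leaf replicate 1, transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2.

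Stress regulators and hormone genes differed by -4.45 for DREB1G, -2.97 for OsDREB1B, -2.73 for OsDREB1A, -3.16 for OsABA8ox1, 2.18 for RAB16B, 1.42 for RAB16C and 1.17 for DIP1. Heat, defence and metal genes differed by 3.22 for OsHsf-05, 1.59 for OsHsp16.9B, 2.17 for PBZ1, -1.71 for OsChia4a, 1.03 for OsWRKY76, 1.81 for OsNAS3 and 1.46 for OsZIP4. Metabolic genes differed by 2.48 for OsCHS1, 2.78 for OsKO5, -0.83 for OsKSL7, -1.01 for OsAOS2, -1.44 for OsNIA1 and 1.56 for OsAOX1A. Photosynthesis, phosphate and response regulator genes gave -1.34 for OsrbcS, -0.73 for GOS5, -1.18 for OsPHO1;3 and 1.48 for OsRR4. OsrbcS (adjusted p = 0.0642 to 0.0954) did not pass without transgenic leaf replicate 1 or 2 or wild-type panicle replicate 1 or 2. OsPHO1;3 (adjusted p = 0.0542 to 0.137), OsWRKY76 (adjusted p = 0.0503 to 0.145) and OsZIP4 (adjusted p = 0.0555 to 0.147) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsAOS2 (adjusted p = 0.0586 to 0.103) did not pass without transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1. OsKSL7 (adjusted p = 0.0660 to 0.156) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 1, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. GOS5 (adjusted p = 0.0559 to 0.197) did not pass without any of the 8 arrays. DIP1 (adjusted p = 0.0618 to 0.149) did not pass without wild-type leaf replicate 1 or 2, transgenic leaf replicate 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. RAB16C (adjusted p = 0.0506 to 0.0597) did not pass without wild-type panicle replicate 1 or 2. OsRR4 (adjusted p = 0.0508) did not pass without wild-type panicle replicate 2. OsAOX1A (adjusted p = 0.0516 to 0.126) did not pass without transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsHsp16.9B (adjusted p = 0.0684 to 0.0722) did not pass without transgenic leaf replicate 2 or wild-type panicle replicate 1 or 2. OsNAS3 (adjusted p = 0.0586) did not pass without wild-type panicle replicate 1. RAB16B (adjusted p = 0.0572 to 0.0794) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 1 or 2 or wild-type panicle replicate 1 or 2. OsCHS1 (adjusted p = 0.0510 to 0.0700) did not pass without wild-type panicle replicate 2 or transgenic panicle replicate 1 or 2.

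Ribosomal protein genes differed by 0.80 for RPS4, 0.97 for RPL7A-2, 0.99 for RPS7 and 1.08 for RPL11. Other named genes gave 3.61 for PRIN2, 4.22 for OsPIP2;5, 3.24 for mfs1, 2.005 for OsAT4, -2.88 for OsMFT1, -2.55 for CML15 and -2.41 for CML31. The rest were -2.27 for OsBURP02, -1.72 for OsMEL1, -1.46 for PCF5, -1.81 for KIN14K, 1.36 for KRP6, 1.29 for Osem, 1.33 for OsEXPB11 and 1.66 for ML6. Genes with a locus number alone gave 1.39 for LOC4331398, 1.75 for LOC4331398, 6.77 for LOC4351887, 5.77 for LOC4347232, -4.82 for LOC4343399 and 3.00 for LOC4333009. The rises behind the value of 1.75 are lower bounds in both tissues, which were on different scales. The sign of that difference is therefore uncertain, whether or not it passed. 4 probe sets with no name gave -3.25, 4.78, 5.11 and 5.22. OsBURP02 (adjusted p = 0.0556 to 0.107) did not pass without wild-type leaf replicate 2, transgenic leaf replicate 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsMEL1 (adjusted p = 0.0505 to 0.0551), RPL7A-2 (adjusted p = 0.0609 to 0.0701), RPS7 (adjusted p = 0.0625 to 0.0710) and RPL11 (adjusted p = 0.0580 to 0.0582) did not pass without wild-type panicle replicate 1 or 2. PCF5 (adjusted p = 0.0505) did not pass without wild-type panicle replicate 1. RPS4 (adjusted p = 0.0547 to 0.120) and OsAT4 (adjusted p = 0.117 to 0.169) did not pass without transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2. OsEXPB11 (adjusted p = 0.0560 to 0.0927) did not pass without transgenic leaf replicate 1 or 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1. The probe set of LOC4331398 with the difference of 1.39 (adjusted p = 0.0553) did not pass without wild-type panicle replicate 1. The other probe set of LOC4331398, at 1.75, passed in every such fit. A probe set with no name (adjusted p = 0.0734 to 0.0950) and a probe set with no name (adjusted p = 0.0883 to 0.111) did not pass without wild-type leaf replicate 2, wild-type panicle replicate 1 or 2 or transgenic panicle replicate 1 or 2.

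Besides the floral list, 10 lists differed between tissues by camera at its preset correlation, and none of the 11 did with an estimated correlation, where adjusted p was 0.159 to 0.671. Their median differences were 0.60 for panicle meristem and branching, -0.50 for photosynthesis, 0.52 for ribosomal proteins, -0.19 for cell cycle and DNA replication, -0.28 for kinesins, -0.37 for MADS box factors, -0.27 for homeobox and YABBY factors, -0.19 for AP2/ERF factors, 0.74 for dehydrins and LEA and 0.29 for metallothioneins and metal transport. The cell cycle and DNA replication list (adjusted p = 0.0847 to 0.230) did not pass without wild-type leaf replicate 1, transgenic leaf replicate 2, wild-type panicle replicate 1 or transgenic panicle replicate 2. The kinesins list (adjusted p = 0.0775) and the dehydrins and LEA list (adjusted p = 0.0630) did not pass without wild-type leaf replicate 1. The AP2/ERF factors list (adjusted p = 0.0845) and the metallothioneins and metal transport list (adjusted p = 0.108) did not pass without wild-type leaf replicate 2.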

How the results depend on the processing

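The family lists, the percentiles and the fit without a run of predicted-gene probe sets were chosen after seeing the data. Of 8029 recomputed values for 402 named results, 7237 kept their side of the threshold, 627 lost and 154 gained the call. A further 11, of called results, changed sign without passing. Changes of sign in results that did not pass, such as DTH8 in leaves, were not counted apart. Of 1755 recomputed list results, 1681 kept their side of the threshold, 48 lost and 25 gained the call, and 1 passed in the opposite direction. Other changes of direction, as for the defence and jasmonate list in panicles with fry, were not counted apart. Leaving out each array in turn gave 1051 to 3292 calls in leaves, 420 to 1645 in panicles, 630 to 2670 for the difference between tissues and 50975 to 52617 for panicle against leaf, and a lone array was then assumed to vary like the other groups. It gave 1 to 9 lists in leaves, 6 to 9 in panicles and 10 to 11 for the difference. A fit on only the 4 arrays of a comparison gave 325 calls in leaves and 692 in panicles. Such a fit also takes the spread from those arrays alone, so fewer degrees of freedom may not be the only reason. A test against a 1.2-fold change gave 1010, 644 and 1051 for leaves, panicles and the difference. In panicles, array weights gave 2807, probe sets above the median mean 1042 and 1 probe set per gene 726. In leaves, array weights gave 1767. For panicle against leaf, fewer probe sets were tested and passed with a mean of at least 5 (30858), above the median mean (26879) or with 1 probe set per gene (16926). Replicate numbers gave little sign of pairing: deviations of same-numbered arrays correlated at 0.0066 to 0.0651. Such correlations cannot exclude that same-numbered samples were handled together, and the labels do not say. A replicate block shared by the groups gave 2464 calls in leaves, 1624 in panicles and 2188 for the difference, and a replicate block within each tissue 1816, 1097 and 1467. Lists called numbered 0, 1 and 0 for leaves, panicles and the difference with an estimated correlation, against 3, 9 and 11. In leaves, fry called 10 lists and a mean of at least 5 gave 6. Except where construction shows it, as with fewer arrays or probe sets, the cause was not tested. Of 45 called results for flowering genes and largest changes, 28 passed under every alternative run. Of their 894 recomputed values, 57 lost the call with the same sign, and a further 2 changed sign and did not pass. Other probe sets of a gene had the opposite sign without passing: -0.030 for IAA3, -0.22 for OsChia2a, 0.046 for Os4bglu13 and -0.33 for LOC4340325 in leaves, and in panicles -0.065 and -0.020 for HSP81-3, -0.058 for OsNAC6, 0.054 for OsNIA1, 0.031 and 0.23 for OsrbcS and 0.088 for IAA31. For MADS box factors in leaves, fry gave a fall (adjusted p = 0.00307) where camera, with adjusted p = 0.732, gave a rise; the mean was -0.36 and the median 0.05. Leaving out the predicted-gene block gave 2545 calls in leaves and 1502 in panicles. The Ghd7 level on a linear scale was not run, since no probe set is named for it here.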

Other observations

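The genes given next were chosen after their values were seen. Of the tests on the run of predicted-gene probe sets further on, those on genomic DNA and on a single array were chosen after the result was seen, the latter after values of some members on each array, and the reading of the former was revised after its own result and then set back to the bound first written. Some of the strongest changes lay in genes with a locus number alone. LOC4331398 rose by 7.79 ± 0.13 in leaves and 9.54 ± 0.13 in panicles (log2 ± SE), from 2.63 ± 0.01 (SD, n = 2) and 4.38 ± 0.17 in wild type, below the array medians, so these are lower bounds. LOC4340325 rose by 5.41 ± 0.17 and 5.64 ± 0.17, although another probe set of that gene read -0.33 in leaves. Its wild-type leaf value was at percentile 25.1, so the leaf rise is a lower bound. A probe set with no name rose by 7.03 ± 0.18 and 3.78 ± 0.18, from percentiles 48.8 and 29.8 in wild type, which are lower bounds too. LOC4347232 rose by at least 5.55 ± 0.14 in panicles, from percentile 33.6, and read -0.22 ± 0.14 in leaves, where both values were below the array median (percentiles 25.4 and 19.9). LOC4351887 fell in leaves, with -6.39 ± 0.25, to percentile 10.3, again a lower bound.

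A run of 262 predicted-gene probe sets, numbered 32184 to 32350 and all but 1 unnamed, had a wild-type median of 10.17 in panicles and 6.11 in leaves, against 6.11 and 4.49 for all other probe sets, although levels of different probes are not comparable. In transgenic panicles the median change was -0.46, with 88 members passing as lower and 2 as higher. In leaves it was 0.16, with 1 lower and 12 higher. The run was not tested as a group.

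A single aberrant transgenic array is argued against, since the weaker of the array medians was -0.27 and the stronger -0.70. For lower organelle transcripts, the probe sets named for organelle genes had a median of -0.76, which met the bound set beforehand for that explanation. It still cannot be told apart, because only 2 probe sets are so named, both outside the run. For genomic DNA from the whole genome in the wild-type samples, antisense probe sets elsewhere met the bound set against it. Their median was 0.043 and their lower quartile -0.091, where such DNA would lower them too. Antisense was read from the probe set name alone, and the probe set used for OsMADS58 carries such a name. These probe sets may therefore measure transcripts, so meeting the bound does not exclude DNA. DNA of the sequences of the run alone was not tested. The median change was -0.63 for antisense members of the run, of which 49 of 134 passed as lower, and -0.27 for sense members, of which 39 of 128 did. No biological explanation was tested.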
